A study of Mus musculus with 24 samples.

How the data were processed

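Hippocampal RNA of 24 male mice was measured on Agilent one-colour arrays, 1 array per animal, each array holding 62976 spots of which 3671 were controls. The labels give 6 groups. WT_CTR (n = 4) and WT_WASHOUT (n = 5) were non-transgenic, and APP-PS1_CTR (n = 3), APP-PS1_UA (n = 4), APP-PS1_WASHOUT (n = 3) and APP-PS1_UA-WASHOUT (n = 5) carried the APP/PS1 transgenes. Urolithin A or water was given by daily gavage from 2 to 7 months of age, and the washout groups lived 1 month longer without gavage. The sources disagree on the dose, which is 200 mg/kg/day in the treatment protocol and 20 mg/kg/day in the series design text. They also disagree on age, since the sample characteristics give 8 months, and 9 months for the washout groups, while the design text places collection at 7 months and 1 month later. P-values measure the spread between animals of the same group. In contrasts whose groups lay wholly on different array slides, described below, they do not measure how far slides differ. Nor do they measure how far array rows differ where the groups filled different rows, as APP-PS1_CTR and WT_CTR did. APP-PS1_UA lay on slides 1 and 2, so its spread between animals also holds any slide difference.

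The deposited scanner files hold spot intensities made by the authors with Feature Extraction 12.0.3.1, per the file headers. Their processed signal is an intensity on a linear scale from which the software had subtracted the background within each array, and it was not normalized between arrays. The deposited series matrix holds a score, for which each array's log signal was standardized to mean 0 and SD 1 over all spots. That was tested on the files, where every value lay within 0.01 of the standardized log of the processed signal. The medians of its columns ran from -0.17 to -0.06. The scale in log units is lost in such a score, the log base cannot be told from it, the centring is on the mean of each array, and a higher score means a higher signal. The authors' statistical test is not given in the sources used here.

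Values for the comparisons were computed from the processed signal. Spots with a software outlier flag were left out (931 values among the probes kept), repeated spots of a probe were averaged as log2 values, and each array's 75th percentile was subtracted. A probe was kept if its signal was well above background, by the software's flag, on at least 3 arrays, which left 43988 of 56605 probes. At least 2 values without a flag were needed in each group, which removed 15 of the kept probes. A gene was represented by its kept probe with the highest mean signal. Probes for which the reference held no symbol (23611 of 56605) were tested as they stood, so the 35259 features tested are 18566 genes with a symbol and 16693 probes without one, and all are called genes here.

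Depth was judged by signal over background. Between 63.7% and 76.9% of the spots of an array were well above background, the 75th percentile of the processed signal lay between 1285 and 2292, and 0 spots were saturated. The number of arrays limits the precision. The 24 arrays lay on 3 slides of 8, as read from the file headers. Slide 1 held all of WT_CTR and APP-PS1_CTR and APP-PS1_UA replicate 1. Slide 2 held the other 3 APP-PS1_UA arrays and all of WT_WASHOUT. Slide 3 held all of APP-PS1_WASHOUT and APP-PS1_UA-WASHOUT. Within slide 1 the WT_CTR arrays filled array row 1 and the transgenic arrays row 2, and on slide 3 row 1 held APP-PS1_WASHOUT with APP-PS1_UA-WASHOUT replicate 1.

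The tests were made in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes), and the tables and plots in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. One model with 6 group means was fitted to all 24 arrays, so that the groups shared an estimate of the spread. In all 8 contrasts were tested, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the contrast. The groups, contrasts, alternatives, gene lists and the rule for named genes were chosen before the data were examined, apart from the alternatives said below to be later.

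Gene lists were tested in the first 4 contrasts with camera at its preset correlation of 0.01, and p-values were adjusted over 26 lists in 4 contrasts (104 tests). The lists covered plaque-associated microglia, homeostatic microglia, complement and antigen presentation, interferon response, inflammatory cytokines and inflammasome, reactive astrocytes and astrocyte identity. Others covered autophagy and mitophagy, lysosome, oxidative phosphorylation, mitochondrial biogenesis, DNA repair, AHR and NRF2 targets, the integrated stress response, heat shock and immediate early genes. The rest were markers of glutamatergic synapses, GABAergic interneurons, hippocampal subfields, neurogenesis and proliferation, oligodendrocytes and myelin, choroid plexus, endothelium, meninges and fibroblasts, blood cells, and striatum, thalamus and cortex. A further list, the transgene check, was reported gene by gene for App and Prnp. The lists were written from general knowledge and hold 461 symbols. Among those not measured above the filter, or without a named probe, were Clec7a, Mx1, Il1a, Steap4, Tgm1, Cox5b, Cyp1a2, Draxin, Cd8a, Adora2a and Rorb. Some genes stand on 2 lists, such as Ctsb, Ctsd, Ctsl and Ctsz (plaque-associated microglia and lysosome).

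Genes named in the text followed a rule. In the first 4 contrasts these were the 12 called genes with the largest rise and the 12 with the largest fall, leaving out clone, predicted and locus symbols, and where fewer than 10 passed also the 5 rises and 5 falls with the smallest p. The contrast of APP-PS1_UA-WASHOUT with APP-PS1_WASHOUT had 23 calls, but only 9 carried a symbol, so the last part was applied there too. From each list up to 4 members with the smallest p could be named, 11 genes were always looked at, and the other contrasts gave 5 rises and 5 falls. Where one group was not well above background on any array, the change is given as a bound against the background limit.

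Transgene scores were compared with exact two-sided permutation tests. The per-array score was the mean, with signs aligned, of the genes called in a contrast that shares no arrays with the groups scored. The fits were also tested on simulated data, in which changes planted in 200 of 35259 genes were called in 54% to 59.5% of cases at a log2 change of 1 and in 86.5% to 92% at 2, with 3 to 15 false calls. The simulated noise was independent between genes and arrays and held no slide or array row difference, so these rates need not hold for the real arrays.

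The alternatives chosen beforehand were quantile normalization, median centring, no filter, a filter on all arrays, every probe by itself, the mean of a gene's probes and the series matrix values. They also were a fit of only the groups compared, a trended robust spread, array weights, blocks for slide, array row and replicate number, fits within 1 slide, leaving out each array, and camera with an estimated correlation. Chosen after seeing the data were normexp (offset 50) on median signals, in place of mean signals that the files lacked, fits without slide 3 or with array row 1 of slide 3 alone, the choroid plexus score as a covariate, leaving out WT_WASHOUT replicates 2 and 3 together, and the plaque-associated list as a score.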

Results

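The hippocampal transcriptomes came from 24 mice in 6 groups of 3 to 5 animals. APP/PS1 mice carry transgenes that include a mutant amyloid precursor protein, and they form amyloid plaques in the brain. Urolithin A is a metabolite that gut bacteria make from ellagitannins, and it is known as an inducer of mitophagy, the autophagic removal of mitochondria. The treated animals received it from 2 to 7 months of age, and the washout groups then went 1 month without it. Values below are log2 signals relative to each array's 75th percentile, as mean ± SD, and changes are differences of group means with the standard error (SE) of the limma fit. Arrays of the same group correlated across genes at 0.977 to 0.991. The first principal component held 47.1% of the variance and set the 8 arrays of slide 3 apart from the others, and the second held 9.4%.

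**Figure D1:**
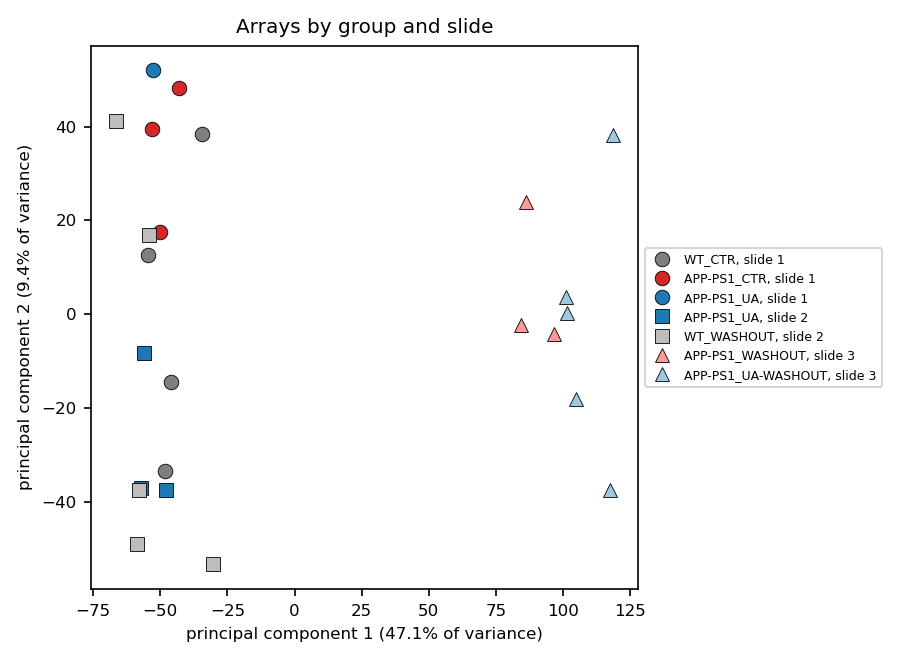
Arrays on the first 2 principal components of the log2 values, coloured by group, with a marker shape for each slide. The first component, with 47.1% of the variance, parts slide 3, which held APP-PS1_WASHOUT and APP-PS1_UA-WASHOUT alone, from slides 1 and 2.

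The first comparison, APP-PS1_CTR with WT_CTR, asked what the transgenes change in water-treated animals at the end of treatment. Several of the genes called singly were transcripts of microglia at amyloid plaques. Cst7, which encodes the cysteine protease inhibitor cystatin F, rose 60.6-fold (log2 change 5.92, SE 0.36, adjusted p = 1.65e-08 by limma), from -5.32 ± 0.62 (n = 4) to 0.60 ± 0.19 (n = 3). Itgax, the integrin CD11c of activated microglia, rose 7.97-fold (log2 3.00, SE 0.31, adjusted p = 4.21e-05). The chemokines Ccl4 (6.95-fold) and Ccl3 (6.52-fold), the inhibitory receptor Lilrb4a (log2 2.34), the chemokine Ccl6 (1.69), the fatty acid receptor Gpr84 (1.54), the immune receptor Slamf9 (1.53) and the survival factor Bcl2a1d (2.84-fold) also rose. Trem2, a lipid receptor that drives the microglial response to plaques, rose 2.13-fold (log2 1.09, SE 0.17, adjusted p = 0.00606), from 1.91 ± 0.10 to 3.00 ± 0.03, and its signalling partner Tyrobp rose by 1.11 (adjusted p = 0.00185). Each of these genes was higher in 3 of 3 transgenic arrays than in every WT_CTR array.

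Of the 29 measured plaque-associated microglial genes, 10 were higher, 0 were lower and 19 did not pass, and adjusted over the list alone 16 were higher. The median change of this list was 0.61 (adjusted p = 5.58e-33, 3 of 3 arrays above the WT_CTR mean), and it kept its call with adjusted p = 0.00711 with an estimated correlation. The lipid carrier Apoe (log2 0.03, adjusted p = 0.969) and the cathepsin Ctsz (0.70, adjusted p = 0.224) did not pass. The list's median ran from 0.58 to 0.71 when any 1 array was left out.

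Complement and antigen presentation genes were 3 higher of 18 measured (8 adjusted over the list alone, 0 lower), with a median of 0.51 (adjusted p = 8.37e-14, and adjusted p = 0.123 with an estimated correlation). When 1 array was left out the median ran from 0.36 (without WT_CTR 2) to 0.80 (without APP-PS1_CTR 1), and the call held. Complement C4b rose by 1.14 (adjusted p = 0.00474), the inhibitory Fc receptor Fcgr2b by 1.30 (0.0195) and the activating Fc receptor Fcgr1 by 0.76 (0.0471). Among 16 homeostatic microglial genes 1 was higher (6 adjusted over the list alone), the Fc receptor-like gene Fcrls (0.71, adjusted p = 0.0361). The median of that list was 0.31 (adjusted p = 5.68e-08, and adjusted p = 0.123 with an estimated correlation). Reactive astrocyte genes were 4 higher of 15 (5 adjusted over the list alone), with a median of 0.40 (adjusted p = 1.2e-07, and adjusted p = 0.123 with an estimated correlation). With 1 array left out the call held, and this median ran from 0.26 (without WT_CTR 2) to 0.50 (without WT_CTR 1). Gfap, the intermediate filament of reactive astrocytes, rose 1.94-fold (log2 0.96, SE 0.19, adjusted p = 0.0471), from 2.99 ± 0.15 (n = 4) to 3.94 ± 0.08 (n = 3). The oncostatin M receptor Osmr (0.88), the endotoxin co-receptor Cd14 (0.92) and the asparaginase Aspg (1.11) rose with it.

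Lysosomal genes passed as a list with a median of 0.18 (adjusted p = 5.5e-07, and adjusted p = 0.123 with an estimated correlation). None of the 27 members passed alone over all genes, and 8 did adjusted over the list alone. Interferon-response genes had a median of 0.35 (adjusted p = 5.81e-05, and adjusted p = 0.829 with an estimated correlation) with 0 of 17 members called either way. Without APP-PS1_CTR 2 the median was 0.07 (adjusted p = 0.466). The inflammatory list had a median of 0.09 (adjusted p = 0.0458, and adjusted p = 0.697 with an estimated correlation). Its called member was the inflammasome adaptor Pycard (0.58, adjusted p = 0.0387), and 2 of 18 passed adjusted over the list alone. The list call was lost without WT_CTR 2 (median 0.19, adjusted p = 0.0524), WT_CTR 4 (0.07, 0.0786), APP-PS1_CTR 2 (0.09, 0.113) or APP-PS1_CTR 3 (0.11, 0.103). Oxidative phosphorylation genes had a median of 0.08 (adjusted p = 0.0117, and adjusted p = 0.829 with an estimated correlation) with 0 of 26 called. That call was lost without WT_CTR 3 (0.205) or APP-PS1_CTR 1 (0.122). Choroid plexus genes had a median of 1.82 (adjusted p = 0.0035, and adjusted p = 0.861 with an estimated correlation) with 0 of 14 called, and without WT_CTR 2 the median was 1.05 (adjusted p = 0.109). The per-array score of this list was 2.32 ± 0.95 in APP-PS1_CTR and 0.46 ± 2.30 in WT_CTR, the groups in which the other lists were compared. With slide as a block, which leaves these differences as they are, the inflammatory list missed the threshold (adjusted p = 0.0509). Within slide 1 the inflammatory (0.0681) and oxidative phosphorylation (0.0688) lists missed it and the other 7 held. An array row block gave a median of 0.33 for plaque-associated microglia (adjusted p = 6.23e-24) and -0.01 for choroid plexus, whose direction reversed, and the inflammatory (0.35) and oxidative phosphorylation (0.129) lists missed the threshold.

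In all, 60 genes passed, 59 higher and 1 lower, and 51 of them carried a symbol. The fall was Wdfy1, an endosomal adaptor of toll-like receptor signalling (log2 -1.59, SE 0.13, adjusted p = 9.34e-07), for which 3 probes gave changes from -1.59 to 0.02. Of the transgene check, Prnp rose 2.81-fold (log2 1.49, adjusted p = 2e-08) by the probe with the higher signal and was -0.10 by its other probe. The vectors of this line use the mouse prion protein promoter. App was 0.24 higher (adjusted p = 0.768). The contrast lay within slide 1, and the groups filled different array rows. A slide block, which changes the spread and not these differences, left 42 genes, all among the 60. Fitted on slide 1 alone 28 passed (17 shared), and with array row as a block 8 passed. Of 25 named genes, Cst7, Itgax, Ccl4, Slamf9, Prnp and Wdfy1 passed with the array row block. Within slide 1 the adjusted p was 0.0664 for Gfap, C4b and Cd14, 0.0536 for Lilrb4a and Slamf9, 0.0501 for Ccl6, 0.0586 for Fcgr2b, 0.125 for Fcgr1, 0.214 for Pycard, 0.234 for Aspg, and 0.255 for Osmr and Fcrls. A slide block gave 0.0589 for Gfap, 0.0578 for Aspg, 0.0516 for Cd14, 0.0632 for Fcgr1 and 0.0505 for Fcrls.

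The count of 60 rested on every array, and it was 32, 28, 32 and 33 without WT_CTR 1, 2, 3 and 4, and 32, 26 and 21 without APP-PS1_CTR 1, 2 and 3. Cst7, Itgax, Ccl4, Ccl3, Lilrb4a, Ccl6, Gpr84, Slamf9, Bcl2a1d, Tyrobp, Prnp and Wdfy1 passed whichever of the 7 arrays was left out. Trem2 missed the threshold without APP-PS1_CTR 3 (adjusted p = 0.0503), and C4b (0.0611) and Osmr (0.11) missed it without APP-PS1_CTR 2. Fcgr2b missed it without WT_CTR 1 (0.0611), WT_CTR 4 (0.0655), APP-PS1_CTR 2 (0.137) or APP-PS1_CTR 3 (0.161). Gfap (0.0828 to 0.22), Cd14 (0.0551 to 0.21), Fcgr1 (0.0703 to 0.277) and Pycard (0.0614 to 0.244) missed it without any 1 of WT_CTR 1, 2, 3, 4 or APP-PS1_CTR 1, 2, 3. Aspg missed it without any of these but WT_CTR 3 (0.0616 to 0.338), and Fcrls without any but WT_CTR 4 (0.0703 to 0.194).

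**Figure D2:**
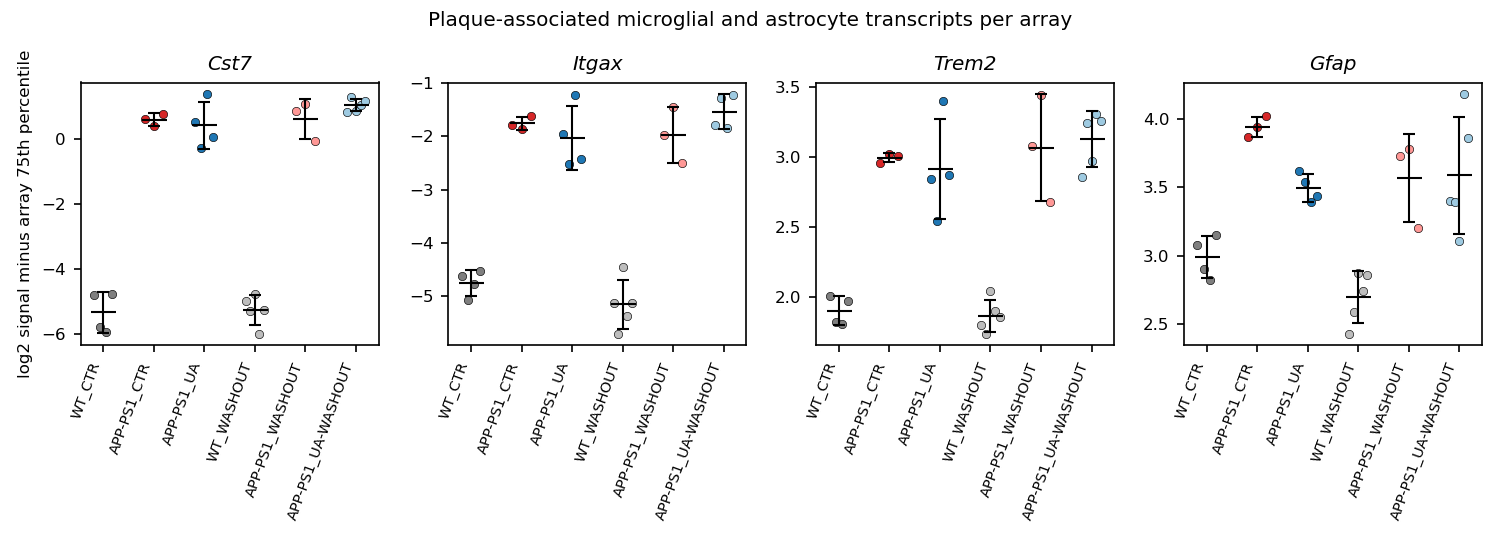
Log2 signal minus the array's 75th percentile of Cst7, Itgax, Trem2 and Gfap, with a point for each array and the mean ± SD for each of the 6 groups. Cst7 lies at 0.60 ± 0.19 in APP-PS1_CTR, 0.42 ± 0.71 in APP-PS1_UA and -5.32 ± 0.62 in WT_CTR.

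APP-PS1_UA was compared with APP-PS1_CTR to find what urolithin A changes in transgenic animals at the end of treatment. Cst7 was 0.42 ± 0.71 (n = 4) with urolithin A and 0.60 ± 0.19 (n = 3) without (log2 change -0.18, adjusted p = 0.922 by limma), and Trem2 was 2.92 ± 0.36 and 3.00 ± 0.03 (-0.09, adjusted p = 0.924). Itgax was -0.27 (adjusted p = 0.837) and Gfap -0.45 (SE 0.19, adjusted p = 0.663), with Gfap at 3.50 ± 0.10 and 3.94 ± 0.08. The mitophagy kinase Pink1 was -0.12 (adjusted p = 0.763), the mitophagy receptor Bnip3 0.21 (0.637) and the autophagy-initiating kinase Ulk1 0.24 (0.638). By limma 0 genes passed, with 2623 at an unadjusted p under 0.05 where 1763 would be expected by chance. With slide as a block 9 passed, with slide and array row as blocks 9, with array weights 6, and within slide 1, with 1 treated array, 0. Without APP-PS1_CTR 1 the count was 1, and without APP-PS1_CTR 2 it was 3. The smallest adjusted p was 0.143, for the growth factor Nrg4 (log2 1.20, SE 0.19), whose 3 probes gave -0.58 to 1.20. After it came the olfactory receptor Olfr665 (-1.67, adjusted p = 0.191), the sphingolipid enzyme relative Samd8 (0.58, 0.601) and, each at 0.637, Slmap (0.36), Elmod2 (1.09), Zmym1 (1.84), Sox12 (-0.57), Mfsd2b (-1.07) and Olfr1333 (-0.99). Tas2r118 was not well above background on any treated array.

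As lists, 5 groups of genes lay lower with urolithin A and 1 higher, with 0 members called in any of them, over all genes or adjusted over the list alone. Complement and antigen presentation had a median of -0.28 (adjusted p = 0.00218, and adjusted p = 0.829 with an estimated correlation), with 0 of 18 members above 0 and complement C3 at -0.97. Reactive astrocyte genes had a median of -0.29 (adjusted p = 0.00344, and adjusted p = 0.757 with an estimated correlation), with the filament Vim at -0.43. Oligodendrocyte and myelin genes had a median of -0.31 (adjusted p = 0.00727, and adjusted p = 0.829 with an estimated correlation), with the transcription factors Olig1 at -0.40 and Sox10 at -0.51, while myelin basic protein (Mbp) was 0.44 by the probe used and as low as -0.60 by another. Plaque-associated microglia had a median of -0.18 (adjusted p = 0.0311, and adjusted p = 0.829 with an estimated correlation), a mean of -0.06 and 3 of 29 members above 0, with Gpnmb at -0.73 and Cd9 at -0.45. Choroid plexus had a median of -2.44 (adjusted p = 0.000388, and adjusted p = 0.829 with an estimated correlation), with transthyretin (Ttr) at 4.15 ± 2.96 and 6.99 ± 0.12. Heat shock genes had a median of 0.15 (adjusted p = 0.0472, and adjusted p = 0.829 with an estimated correlation), with Hsp90aa1 at 0.33 and Dnajb1 at 0.34. The choroid plexus score was -0.03 ± 2.77 in APP-PS1_UA and 2.32 ± 0.95 in APP-PS1_CTR. Complement, reactive astrocyte and heat shock scores lay on the side of the change in 4 of 4 treated arrays, oligodendrocyte and choroid plexus scores in 3, and plaque-associated scores in 2.

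None of these 6 list calls held with slide as a block. The medians were then -0.10 for complement, -0.08 for reactive astrocytes, -0.12 for oligodendrocytes, -0.08 for plaque-associated microglia, 0.07 for heat shock and, reversed, 1.40 for choroid plexus, and the medians within slide 1 were the same. An array row block kept heat shock alone (median 0.26, adjusted p = 0.00215). Only 1 treated array, APP-PS1_UA 1, shared a slide with APP-PS1_CTR. Without APP-PS1_UA 4 all 6 were lost, with medians of -0.16 for complement (adjusted p = 0.0987), -0.21 for reactive astrocytes (0.0551), -0.23 for oligodendrocytes (0.11), -0.08 for plaque-associated microglia (0.356), -1.58 for choroid plexus (0.0551) and 0.14 for heat shock (0.063). Complement was also lost without APP-PS1_CTR 3 (0.053) and oligodendrocytes without APP-PS1_CTR 1 (0.0542). Plaque-associated microglia was lost without APP-PS1_CTR 2 (0.0654) or APP-PS1_UA 2 (0.244), and heat shock without APP-PS1_CTR 2 (0.106), APP-PS1_UA 2 (0.109) or APP-PS1_UA 3 (0.054).

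APP-PS1_WASHOUT was compared with WT_WASHOUT for the transgene effect 1 month later. Slide 3 held all the transgenic arrays and slide 2 all the non-transgenic ones, so no slide held both groups. Cst7 rose 58.6-fold (log2 5.87, SE 0.35, adjusted p = 4.35e-10 by limma), from -5.25 ± 0.46 (n = 5) to 0.62 ± 0.61 (n = 3), levels that lay beside the -5.32 and 0.60 of WT_CTR and APP-PS1_CTR on slide 1. Itgax rose by 3.18 (adjusted p = 1.88e-07), Ccl3 by 3.23 and Ccl4 by 2.71, and Trem2 rose 2.30-fold (log2 1.20, SE 0.17, adjusted p = 1.59e-05), from 1.87 ± 0.11 to 3.07 ± 0.38. Prnp rose by 1.40 (adjusted p = 1.85e-09) by one probe and was -0.12 by the other, and App was 0.14 (adjusted p = 0.355). Plaque-associated microglia were 18 higher, 0 lower and 11 not passed of 29 (19 higher and 1 lower adjusted over the list alone), with a median of 0.48 (adjusted p = 5.15e-06, and adjusted p = 0.697 with an estimated correlation). Complement genes were 8 higher of 18, with the same number adjusted over the list alone. Their median was 0.69 (adjusted p = 0.00806, and adjusted p = 0.829 with an estimated correlation), with C4b at 1.27 and the anaphylatoxin receptor C3ar1 at 1.40. Without APP-PS1_WASHOUT 2 this median was 0.51 (adjusted p = 0.0905). Homeostatic microglial genes were 8 higher of 16 (9 adjusted over the list alone), among them Fcrls (1.17), the selectin ligand Selplg (0.67) and Aif1, the calcium-binding protein Iba1 (0.81). Their median was 0.41 (adjusted p = 0.00913, and adjusted p = 0.829 with an estimated correlation), and without APP-PS1_WASHOUT 2 it was 0.33 (adjusted p = 0.0859).

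Immediate early genes, which neuronal activity or handling at collection induces, were 9 lower of 19 (9 adjusted over the list alone), with a median of -0.66 (adjusted p = 7.98e-05, and adjusted p = 0.829 with an estimated correlation). The score of this list was 1.96 ± 0.08 in WT_WASHOUT and 1.21 ± 0.24 in APP-PS1_WASHOUT, and its means in the other 4 groups ran from 1.02 to 1.14, so WT_WASHOUT stood apart. The phosphatase Dusp1 was lower than in WT_WASHOUT by 1.42, the matricellular gene Ccn1 by 1.32, the early response gene Ier2 by 1.25 and the growth suppressor Btg2 by 1.17. Each of these 4 lists had 3 of 3 transgenic arrays on the side of the change. Reactive astrocyte genes were 4 higher of 15 (6 higher and 1 lower adjusted over the list alone), with Gfap at 0.87 (adjusted p = 0.00128), and the list did not pass (median 0.42, adjusted p = 0.215). Called members of lists that did not pass included the nitric oxide synthase Nos2 (2.32) and the cytokine Tnf (0.96) of the inflammatory list (5 higher and 1 lower of 18), which rose, and the interneuron transcription factor Lhx6 (-1.11) and the GABA-making enzyme Gad1 (-0.50) of the interneuron list (1 higher and 4 lower of 15), which fell. The helicase Wrn (-1.60) of the DNA repair list (2 higher and 5 lower of 29) and the chaperones Hspa1a (-0.82) and Dnajb1 (-0.84) of the heat shock list (0 higher and 3 lower of 11) were lower, with a heat shock score of 4.36 ± 0.14 in WT_WASHOUT and means of 3.96 to 4.14 in the other 5 groups, and the lysosomal enzymes Gla (0.99) and Ctsb (0.51) rose (6 higher and 1 lower of 27).

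In all 9702 genes passed, 6984 higher and 2718 lower, with 13363 at an unadjusted p under 0.05 and a median change over all genes of 0.07. Quantile normalization moved that median by -0.14 and median centring by -0.23, and the balance turned, with 4452 higher and 5251 lower under the first and 4976 and 7874 under the second, while the 4 list calls held under both. Without WT_WASHOUT 2 and 3 together 7863 passed, 7426 of them shared. Apoe was 0.36 (adjusted p = 0.0184) and became -0.10 with quantile normalization, and it missed the threshold without APP-PS1_WASHOUT 1 (adjusted p = 0.0627) or 2 (0.0604). Large rises beside that of Cst7 included the nuclear pore relative Pom121l2 (at least 41.9-fold, adjusted p = 2.95e-12), Cmtm2b (at least 20.6-fold), the olfactory receptor Olfr715b (at least 18-fold) and the epidermal caspase Casp14 (at least 16.5-fold), each against WT_WASHOUT arrays that were not well above background. Pom121l2 was well above background on 0 arrays of WT_CTR, APP-PS1_CTR and APP-PS1_UA too, and Cmtm2b was so on 3 WT_CTR arrays. Among the called falls were the major urinary protein genes Mup17 (-5.36) and Mup18 (-5.32), which without WT_WASHOUT 2 and 3 together were -2.86 (adjusted p = 0.0385) and -2.78 (0.0325), the chemokine Cxcl1 (-2.23) and Wdfy1 (-1.81, with probes from -1.81 to 4.00). Albumin (Alb), a liver transcript that stood at 1.09 and 0.52 in WT_WASHOUT 2 and 3 and at most -4.65 in the other arrays, fell at least 7.72-fold, and its call was lost without WT_WASHOUT 2 (adjusted p = 0.114), WT_WASHOUT 3 (0.111) or APP-PS1_WASHOUT 1 (0.146), 2 (0.0793) or 3 (0.0954). For scale, 8044 genes passed between APP-PS1_WASHOUT and APP-PS1_CTR, which lie on slides 3 and 1, and 6 passed between WT_WASHOUT and WT_CTR, which lie on slides 2 and 1.

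APP-PS1_UA-WASHOUT was compared with APP-PS1_WASHOUT for what remains of the treatment 1 month after it ends. Cst7 was 1.04 ± 0.19 (n = 5) after urolithin A and 0.62 ± 0.61 (n = 3) after water (log2 change 0.42, adjusted p = 0.83 by limma), Trem2 was 0.06 (adjusted p = 0.968), Itgax 0.44 (0.787), Gfap 0.02 (0.991) and Pink1 -0.09 (0.876). In all 23 genes passed, 8 higher and 15 lower, with 2698 at an unadjusted p under 0.05, and 9 of the 23 carried a symbol. The count depended on the processing, with 4 by normexp, 89 by quantile normalization, 306 by the series matrix values, 2862 without a filter, 4 with the filter on all arrays and 81 with slide and array row as blocks. Nhlh2, a neuronal transcription factor, fell 2.21-fold (log2 -1.14, SE 0.19, adjusted p = 0.0208), from -2.99 ± 0.31 to -4.13 ± 0.27, and the small membrane protein gene Smco4 rose 2.46-fold (1.30, SE 0.22, adjusted p = 0.025), from 0.79 ± 0.51 to 2.09 ± 0.28, each in 5 of 5 treated arrays. Another, Gm31992 (1.05, adjusted p = 0.0321), lies outside the rule for named genes and was chosen after its values were seen. The other 6 were not well above background on any treated array. Array row 2 of slide 3, which held 4 of the 5 treated arrays and no untreated one, had 63.7% to 69.9% of its spots well above background, against 73.8% to 76.9% in row 1. These 6 genes were the TATA-binding protein relative Tbpl2 (at least 3.03-fold lower, adjusted p = 1.89e-06), Tprg (at least 3.09-fold), the chemokine receptor Cxcr1 (at least 2.16-fold), Olfr1314 (at least 1.87-fold), the phosphatase Ppm1n (at least 1.56-fold, with probes from -2.37 to 2.13) and Psg27 (at least 1.25-fold). Tbpl2, Cxcr1, Olfr1314 and Psg27 were well above background on the 3 APP-PS1_WASHOUT arrays alone, so they passed the filter only through that group. Without the filter Tbpl2 was read by another probe, and its change reversed. Pramel20 (1.67, adjusted p = 0.0654), Cngb3, Pdia5 (0.78) and Vax2 (each of the last 3 at 0.131) did not pass. Slide as a block cannot absorb any of this contrast, since slide 3 held all 8 arrays, and within slide 3 alone 0 genes passed, with adjusted p from 0.334 to 0.497 for Nhlh2, Smco4 and these 6. The count was 86 without APP-PS1_WASHOUT 2, 52 without APP-PS1_UA-WASHOUT 1, 15 without APP-PS1_UA-WASHOUT 4 and 14 without APP-PS1_UA-WASHOUT 5. Nhlh2 and Smco4 missed the threshold without APP-PS1_WASHOUT 1 (adjusted p = 0.156 and 0.178), APP-PS1_WASHOUT 3 (0.0728 and 0.152), APP-PS1_UA-WASHOUT 4 (0.0569 for both) or 5 (0.0522 and 0.066). Tprg missed it without APP-PS1_WASHOUT 2 (0.0523) or 3 (0.206) or APP-PS1_UA-WASHOUT 3 (0.053), 4 (0.0569) or 5 (0.0784).

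Oligodendrocyte and myelin genes lay lower as a list after urolithin A and washout (median -0.37, adjusted p = 0.00153, and adjusted p = 0.829 with an estimated correlation). Of 16 members 2 were above 0 and 0 passed, over all genes or adjusted over the list alone, with the myelin genes Mobp at -0.48 and Opalin at -0.63 and the myelin enzyme Cnp at -0.40. The list score lay below the APP-PS1_WASHOUT mean in 4 of 5 treated arrays, but APP-PS1_UA-WASHOUT 5 (2.781) all but equalled that mean (2.784). APP-PS1_UA-WASHOUT 4 (2.917) lay above every untreated array (2.663 to 2.885), so the groups overlapped. Within slide 3 the oligodendrocyte call held (adjusted p = 0.0142), and it was lost without APP-PS1_UA-WASHOUT 2 (median -0.28, adjusted p = 0.0549) or 3 (-0.24, 0.0615). Astrocyte identity genes had a median of -0.10 (adjusted p = 0.0312, and adjusted p = 0.829 with an estimated correlation), with the bicarbonate transporter Slc4a4 at -0.28 and the transcription factor Sox9 at -0.37. That call was lost within slide 3 (adjusted p = 0.117) and without APP-PS1_WASHOUT 2 (0.0859) or 3 (0.174) or APP-PS1_UA-WASHOUT 1 (0.288), 2 (0.0549), 4 (0.105) or 5 (0.0906). The median of this list ran from -0.17 (without APP-PS1_UA-WASHOUT 3) to -0.05 (without APP-PS1_UA-WASHOUT 1). The plaque-associated list was 0.08 (adjusted p = 0.144), complement -0.02 (0.809) and reactive astrocytes -0.02 (0.763).

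**Figure D3:**
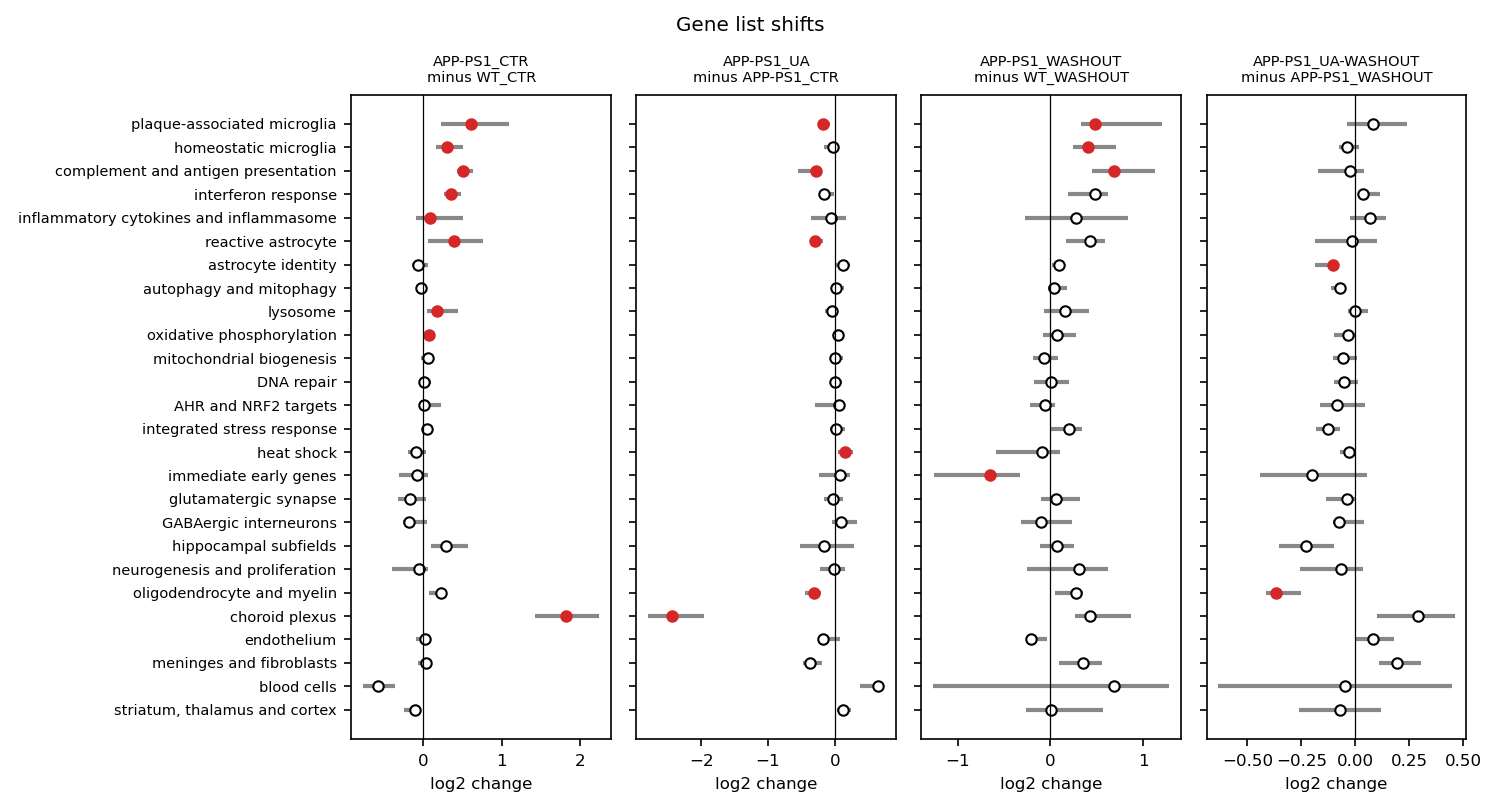
Median log2 change of each gene list (points) with the interquartile range of its members (bars) in the 4 contrasts tested with camera, filled red where the adjusted p was under 0.05. The plaque-associated microglia list lies at 0.61 and 0.48 in the contrasts of transgenic with non-transgenic animals and at -0.18 and 0.08 in those of urolithin A with water.

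Some 13 of the 26 lists passed in none of the 4 contrasts. For autophagy and mitophagy, the process that urolithin A is known for, the medians with urolithin A were 0.02 (adjusted p = 0.215) at the end of treatment and -0.07 (0.13) after washout. The score of this list was 2.43 to 2.52 in APP-PS1_UA, 2.39 to 2.42 in APP-PS1_CTR and 2.32 to 2.52 in WT_CTR. Of the APP-PS1_UA arrays 3 lay on another slide than APP-PS1_CTR. After washout 5 of 5 treated arrays lay below the untreated mean. Mitochondrial biogenesis was 0.00 (0.99) and -0.06 (0.478), and DNA repair 0.00 (0.96) and -0.06 (0.509). AHR and NRF2 targets, which respond to foreign compounds and oxidants, were 0.06 (0.603) and -0.09 (0.294), and the integrated stress response was 0.01 (0.958) and -0.13 (0.102). Glutamatergic synapse genes were -0.02 (0.909) and -0.04 (0.42), GABAergic interneurons 0.10 (0.215) and -0.08 (0.5), hippocampal subfields -0.16 (0.528) and -0.23 (0.134), and neurogenesis and proliferation -0.02 (0.809) and -0.07 (0.909). Endothelium was -0.18 (0.26) and 0.08 (0.127), meninges and fibroblasts -0.38 (0.31) and 0.19 (0.528), blood cells 0.65 (0.0997) and -0.05 (0.5), and striatum, thalamus and cortex 0.13 (0.23) and -0.07 (0.669). In the transgene contrasts the smallest adjusted p among these 13 was 0.0523, for endothelium after washout (median -0.21). The median, mean and test differed in sign for the integrated stress response and meninges in APP-PS1_CTR against WT_CTR, and for autophagy, DNA repair, subfields, choroid plexus and striatum in APP-PS1_WASHOUT against WT_WASHOUT. They also differed for mitochondrial biogenesis, DNA repair, AHR and NRF2 targets, the integrated stress response and neurogenesis with urolithin A at the end of treatment, and for the lysosome after washout.

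Treated transgenic animals were also compared with non-transgenic ones. Between APP-PS1_UA and WT_CTR 22 genes passed, 20 higher and 2 lower, with Cst7 at 5.74 (adjusted p = 5.38e-09 by limma), Itgax at 2.72 (5.7e-05), Ccl3 at 2.50 (0.00464), Ccl4 at 2.46 (5.7e-05), Lilrb4a at 1.84 (0.0105) and Wdfy1 at -1.78 (2.81e-08). With slide as a block 18 passed (6 shared), and Ccl3 (adjusted p = 0.125) and Lilrb4a (0.162) did not. The fit within slide 1, with 1 treated array, called 6 (3 shared). The count was 13, 12 and 11 without WT_CTR 1, 2 and 3, and 7 without APP-PS1_UA 3, and Lilrb4a was lost without WT_CTR 2 (0.0526) or APP-PS1_UA 3 (0.0633). Between APP-PS1_UA-WASHOUT and WT_WASHOUT, again on separate slides, 12805 passed, 8097 higher and 4708 lower. The largest included Cst7 at 6.29 (7.96e-12), Plaat5, a phospholipase, at 6.10 and Mup18 at -4.80, which was -2.26 (adjusted p = 0.0412) without WT_WASHOUT 2 and 3. Median centring moved the median change of all genes there by -0.29, from 0.03, and gave 5788 higher and 13898 lower.

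Whether effects differed between the stages was tested directly. The urolithin A effect differed for 3 genes, each lower after washout, which were Tbpl2 (adjusted p = 0.000541 by limma), Cxcr1 (0.0428) and Olfr1314 (0.0428). Each was well above background on the 3 APP-PS1_WASHOUT arrays and on 0 arrays of the other 5 groups, so no size is given. Their probes passed the filter of 3 arrays through that group alone, so the calls rest on its values being high. With slide as a block 1 passed, Tbpl2, while Cxcr1 (0.373) and Olfr1314 (0.0762) did not. Without the filter Tbpl2 was read by another probe, and its stage difference reversed. When any 1 of the 15 arrays was left out, Cxcr1 kept its call only without APP-PS1_WASHOUT 1, 2 or 3 or APP-PS1_UA-WASHOUT 2, and Olfr1314 only without APP-PS1_WASHOUT 2 or APP-PS1_UA-WASHOUT 2 or 4 (adjusted p = 0.0514 to 0.137 without the others, for both). The count ran from 1 to 28. It was 1 without APP-PS1_CTR 1 or 3, APP-PS1_UA 2, 3 or 4, or APP-PS1_UA-WASHOUT 3 or 5. It was 5 without APP-PS1_CTR 2 or APP-PS1_UA-WASHOUT 2, 6 without APP-PS1_WASHOUT 3 and 28 without APP-PS1_WASHOUT 2. The transgene effect differed for 5029 genes, 4096 higher and 933 lower after washout, a contrast in which slide and group cannot be told apart. Quantile normalization moved its median change over all genes by -0.15, from 0.09, and gave 2263 higher and 1757 lower, and median centring moved it by -0.27 and gave 3028 and 4016. Plaat5 rose (5.20), and Cmtm2b, Pom121l2, Casp14 and Dio3os were called higher without a size, since 1 group compared (APP-PS1_CTR for Dio3os and WT_WASHOUT for the others) was not well above background on any array. The falls included the cholesterol hydroxylase Ch25h (-2.55) and the hyaluronan synthase Has3 (-1.94), whose call was lost without WT_CTR 1 (adjusted p = 0.0535), APP-PS1_CTR 1 (0.0641) or APP-PS1_WASHOUT 3 (0.0815).

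Across genes, which are not independent replicates, the 2 transgene contrasts correlated with r = 0.015 (rho = 0.007), and the 2 urolithin A contrasts with r = -0.069 (rho = -0.103), over contrasts that share no arrays. Genes called in one stage were then scored in the other. The score of the 60 genes was -0.78 ± 0.15 in APP-PS1_UA-WASHOUT (n = 5) and -0.87 ± 0.24 in APP-PS1_WASHOUT (n = 3), a difference of 0.08 (exact permutation p = 0.571, adjusted 0.571, smallest possible 0.0179 over 56 splits). The difference turned to -0.04 without APP-PS1_WASHOUT 3 and was 0.20 without APP-PS1_WASHOUT 2. In WT_WASHOUT (n = 5) the score of the 60 genes was -2.24 ± 0.12, with each APP-PS1_WASHOUT array above every WT_WASHOUT array (difference 1.38, exact permutation p = 0.0179, the smallest possible, in a comparison added after the values were seen and outside the adjustment). These arrays lay on slides 3 and 2. Between APP-PS1_UA-WASHOUT on slide 3 and the APP-PS1_UA arrays on slide 2 the score differed by 0.39. That is 28.2% of 1.38 (20.7% to 40% when 1 array was left out). The score of the 9702 genes was -2.55 ± 0.02 in APP-PS1_UA (n = 4) and -2.50 ± 0.02 in APP-PS1_CTR (n = 3), a difference of -0.04 (exact permutation p = 0.0571, adjusted 0.114, smallest possible 0.0286 over 35 splits). The WT_CTR arrays, from -2.58 to -2.39, lay on both sides of APP-PS1_CTR in that score, so it carried no transgene difference at this stage and says nothing on whether urolithin A changes one. APP-PS1_UA replicates 2 to 4 lay on another slide than APP-PS1_CTR.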

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

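The tests that weigh explanations in this part were chosen only after the results were seen, while the counts over other splits of the arrays were set beforehand, except that the split of the plaque-associated list was added once the list counts had been seen.

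The first pattern is the 9702 genes called between APP-PS1_WASHOUT and WT_WASHOUT, such as Pom121l2 and Plaat5. The transgene effect seen at the end of treatment was excluded for the set as a whole, since 48.5% of the called genes had the same sign in APP-PS1_CTR minus WT_CTR (45.5% to 55.7% when 1 array was left out). A difference between slide 3 and the other slides may account for most of it, because 95.1% of the called genes had the same sign in APP-PS1_UA-WASHOUT minus APP-PS1_UA, which shares no arrays with the contrast (r = 0.89 across genes). As the whole cause of the rise of the plaque-associated list, a part of the pattern, slide 3 was argued against. The list score differed by 1.03 between APP-PS1_WASHOUT and WT_WASHOUT and by 0.20, or 19.9% of that (10% to 36.2% when 1 array was left out), between APP-PS1_UA-WASHOUT on slide 3 and APP-PS1_UA replicates 2 to 4 on slide 2. For the other genes a transgene effect that arises in the washout month cannot be told apart from slide 3, which held 0 non-transgenic arrays. Called genes included 195 higher and 4 lower of 336 olfactory, vomeronasal and taste receptor genes (median 1.23, and -0.11 in APP-PS1_CTR minus WT_CTR), and of 5 brightness classes of equal size the dimmest held 3064 higher with 97 lower and the brightest 834 and 658.

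The second pattern is the lower complement, reactive astrocyte, oligodendrocyte and plaque-associated lists, and the higher heat shock list, in APP-PS1_UA against APP-PS1_CTR. With slide as a block the 5 medians kept 37.6% of their size at the median (plaque-associated 46.1%, complement 36.2%, reactive astrocyte 29%, heat shock 44.5%, oligodendrocyte 37.6%), but that block rests on APP-PS1_UA 1 alone, so slide and treatment cannot be told apart. With the choroid plexus score as a covariate they kept 84.4% at the median (84.4%, 67.4%, 47.9%, 89.7% and 87.8% in that order), and the calls ended, so a part for the amount of choroid plexus stays open. Urolithin A lowering plaque-associated microglia also cannot be told apart from these, with scores of 1.63 ± 0.25 (n = 4) and 1.69 ± 0.14 (n = 3) and an exact permutation p of 0.714.

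The third pattern is the 23 genes called between APP-PS1_UA-WASHOUT and APP-PS1_WASHOUT, such as Tbpl2, Cxcr1 and Olfr1314. Signal near background could explain many of them, since 78.3% (18 of 23) had a probe that was not well above background on every array, against 27.2% of all genes tested, but genes silenced by the treatment would raise that share too. Tbpl2, Cxcr1 and Olfr1314 were well above background on 0 arrays of the untreated APP-PS1_CTR as well. They were so on 0 arrays of APP-PS1_UA-WASHOUT, in row 1 or row 2. These 3 genes passed the filter of 3 arrays through APP-PS1_WASHOUT alone. Without the filter Tbpl2 was read by another probe, and its change reversed. An effect of array row 2 of slide 3, which held 4 of the 5 treated arrays, could not be separated either. Its arrays had 63.7% to 69.9% of spots well above background and a negative-control SD of 5.69 to 7.67, against 73.8% to 76.9% and 3.07 to 3.99 in row 1. Among 52 genes called from the row 2 arrays alone, the treated array of row 1 lay at a median position of 0.48 between the untreated mean (0) and the treated mean (1), with 22 genes under 0.25 and 19 over 0.75.

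Chance was tested by splitting the arrays into other groups of the same sizes. It is called excluded where a share under 0.05 of the splits gave as much, without adjustment for the number of such tests. The splits cannot tell a group from the slide or array row that it filled. APP-PS1_CTR and WT_CTR filled different array rows of slide 1. For APP-PS1_CTR against WT_CTR chance can be excluded for the genes (60 called and at most 5 in the other splits, 1 of 35 as large) and for the plaque-associated list (camera p = 5.37e-35 before adjustment, and in a permutation of the arrays over the other splits at lowest 9.13e-27, 1 of 35). It cannot be excluded for the number of lists (9 and at most 14, 9 of 35). For APP-PS1_UA against APP-PS1_CTR the gene count tests nothing, since 0 were called and 35 of 35 splits give as many by definition (at most 1), and chance cannot be excluded for the lists (6 and at most 12, 17 of 35). The plaque-associated list had a camera p of 0.0054 there before adjustment, and at lowest 2.00e-09 in the other splits. Chance cannot be excluded for it either. The split that follows the slides gave 1 gene and 6 lists, as many lists as the treatment. For APP-PS1_WASHOUT against WT_WASHOUT chance can be excluded for the genes (9702 and at most 2349, 1 of 56) and not for the lists (4 and at most 13, 37 of 56). The plaque-associated list had a camera p of 2.97e-07 there before adjustment. In other splits it was 1.29e-10, 3.14e-10, 3.48e-08, 1.12e-07 and 1.21e-07, so the camera p of this list cannot exclude chance. The per-array list score ran from 1.56 to 1.88 in APP-PS1_WASHOUT and from 0.52 to 0.88 in WT_WASHOUT (exact permutation p = 0.0179). This argues against chance for the score, in a comparison chosen after the values were seen and not adjusted. The 2 groups lay on slides 3 and 2. For APP-PS1_UA-WASHOUT against APP-PS1_WASHOUT chance cannot be excluded for the genes (23 and at most 51, 4 of 56) or the lists (1 and at most 14, 55 of 56). The 3 splits with more genes, at 51, 37 and 34, all set the arrays of row 1 with 1 array of row 2 against the rest of row 2, and within slide 3 alone 0 genes passed. Chance can be excluded for APP-PS1_UA against WT_CTR (22 and at most 3, 1 of 35), APP-PS1_UA-WASHOUT against WT_WASHOUT (12805 and at most 5764, 1 of 100) and the stage difference of the transgene effect (5029 and at most 4039, 1 of 100). The split with 4039 kept the 3 APP-PS1_WASHOUT arrays together. For the stage difference of urolithin A 4 of 100 splits gave as many (3 and at most 11), which is under 0.05. These splits were a random draw from those possible, and 4 of 100 lies too close to 0.05 to exclude chance. The list counts here were adjusted within each contrast.

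Samples far from the others of their group were sought in 144 sets of values, where chance gives about 1 in 20, and 4 were found. The inflammatory score of WT_WASHOUT 5 was -2.46 (others -2.96 to -2.85). The heat shock score was 4.20 in WT_CTR 2 (others 3.96 to 3.99) and 4.12 in WT_WASHOUT 1 (others 4.38 to 4.44). Ctsz was 3.11 in APP-PS1_UA-WASHOUT 4 (others 2.53 to 2.66).

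Genes whose effect differed between the stages by the direct limma test were given as the fitted difference, and with both effects where each group compared was well above background on at least 1 array. Of urolithin A these were Tbpl2 (-3.41), Cxcr1 (-3.04) and Olfr1314 (-2.44). Of the transgenes they were Pom121l2 (6.21), Cmtm2b (6.48), Casp14 (5.54), Dio3os (5.19) and Olfr1173 (-2.59). For these 8 genes a group compared was not well above background on any array, so the fitted differences depend on values near the background and are neither sizes nor bounds. The others were Plaat5 (5.20, from -0.12 to 5.08), Ch25h (-2.55, from 1.22 to -1.34), Has3 (-1.94, from 1.02 to -0.92), Slc8a3 (-1.66, from 0.10 to -1.56) and Wrn (-1.66, from 0.06 to -1.60). The call of Has3 was lost without WT_CTR 1 (adjusted p = 0.0535), APP-PS1_CTR 1 (0.0641) or APP-PS1_WASHOUT 3 (0.0815). Those of Cxcr1 and Olfr1314 were lost without any 1 of 11 and 12 of the 15 arrays (0.0514 to 0.137), among them each array of APP-PS1_CTR and APP-PS1_UA. For the transgene genes the later stage compares slide 3 with slide 2, and slide and stage cannot be told apart.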

How the results depend on the processing

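The settings chosen only after the results were seen were normexp on median signals, the fits without slide 3, with array row 1 of slide 3 alone, with the choroid plexus covariate and without WT_WASHOUT 2 and 3, and the plaque-associated score. Where no construction is named, the cause was not tested. The contrasts are named by their groups, and the stage difference is the effect after washout minus that at the end of treatment.

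With normexp 5961 genes passed in APP-PS1_WASHOUT minus WT_WASHOUT (5689 shared with the 9702), 4 in APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT and 2018 in the stage difference of the transgene effect, and Ppm1n reversed to 0.67. With quantile normalization 89 passed in APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT (22 shared) and 23 in the stage difference of urolithin A, and Apoe reversed to -0.10 after washout. Median centring gave 19686 in APP-PS1_UA-WASHOUT minus WT_WASHOUT (10496 shared) and 15 in the stage difference of urolithin A. Without a filter the counts were 31 in APP-PS1_CTR minus WT_CTR (31 shared), 2862 in APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT, 21734 in APP-PS1_UA-WASHOUT minus WT_WASHOUT and 0 in the stage difference of urolithin A. Tbpl2, then read by another probe, reversed to -0.07 (APP-PS1_WASHOUT minus WT_WASHOUT), 2.04 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT) and 1.70 (stage difference). With probes well above background on all arrays, which by construction removes genes that are dim in 1 group only, the counts were 6351 (APP-PS1_WASHOUT minus WT_WASHOUT), 4 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT), 0 (stage difference of urolithin A) and 2958 (of the transgenes). What signal over background limits is thus not shown by that filter. Every probe by itself gave 1 in the stage difference of urolithin A. The mean of a gene's probes reversed Cox7c (0.17), Homer1 (-0.21), Stat2 (0.43) and Wdfy1 (0.21) in APP-PS1_WASHOUT minus WT_WASHOUT and Slc8a3 (0.32) in the stage difference. The series matrix values gave 306 in APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT (23 shared) and 36 in the stage difference of urolithin A, and astrocyte identity reversed to 0.012 in APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT.

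The spread model mattered for small counts. With only the groups compared, so fewer arrays for the spread, 28 passed in APP-PS1_CTR minus WT_CTR (17 shared), 0 in APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT, 5 in APP-PS1_UA minus WT_CTR and 1 in the stage difference of urolithin A. That last count was 0 with a trended robust spread and 40 with array weights, which also gave 140 in APP-PS1_CTR minus WT_CTR (60 shared) and 6 in APP-PS1_UA minus APP-PS1_CTR.

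Blocks changed counts too. Slide as a fixed block gave 9 genes in APP-PS1_UA minus APP-PS1_CTR, 1 in the stage difference of urolithin A and 11 list calls (10 shared) where 17 of the 21 could be estimated, since APP-PS1_WASHOUT minus WT_WASHOUT, with the other 4, has no estimate under that block, and choroid plexus reversed to 1.40 in APP-PS1_UA minus APP-PS1_CTR. Slide as a random block (correlation -0.0588) gave 18 in the stage difference of urolithin A. Within slide 1 the counts were 28 (APP-PS1_CTR minus WT_CTR), 6 (APP-PS1_UA minus WT_CTR) and 11 list calls over those contrasts, with choroid plexus at 1.40, and within slide 3 they were 0 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT) and 1 list call. Array row as a block gave 8 (APP-PS1_CTR minus WT_CTR), 13 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT), 1 (stage difference of urolithin A) and 784 (of the transgenes), and choroid plexus reversed to -0.012 in APP-PS1_CTR minus WT_CTR. Slide and array row together gave 4, 9 (APP-PS1_UA minus APP-PS1_CTR), 81 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT), 5 (APP-PS1_UA minus WT_CTR), 1 and 13 list calls (8 shared, of the same 17), with choroid plexus again at 1.40. Replicate numbers did not pair the samples (2 of 12 pairs correlated above 0.1, from -0.24 to 0.235), and the replicate block gave 34 (APP-PS1_CTR minus WT_CTR), 12 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT), 12 (APP-PS1_UA minus WT_CTR) and 1 (stage difference of urolithin A). Array row 1 of slide 3 alone, with 1 treated array, gave 1. The choroid plexus covariate gave 37 in APP-PS1_CTR minus WT_CTR (36 shared), and by construction took choroid plexus to -0.017 there and 0.013 in APP-PS1_UA minus APP-PS1_CTR. Without WT_WASHOUT 2 and 3 the counts were 7863 in APP-PS1_WASHOUT minus WT_WASHOUT (7426 shared) and 4 list calls, the same 4, in the 1 contrast that setting covers. An estimated correlation left 1 list call, plaque-associated microglia in APP-PS1_CTR minus WT_CTR.

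The correlation of the transgene contrasts (0.015) was 0.073 with normexp, 0.058 with quantile normalization, 0.055 with the filter on all arrays, -0.121 with the row block and 0.051 with the replicate block. That of the urolithin A contrasts (-0.069) was -0.014 without a filter, -0.12 with the filter on all arrays and with the slide block, -0.276 with the row block, 0.004 with the replicate block and -0.143 with the covariate.

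When 1 array was left out the counts ran from 21 to 33 (APP-PS1_CTR minus WT_CTR), 0 to 3 (APP-PS1_UA minus APP-PS1_CTR), 7124 to 10076 (APP-PS1_WASHOUT minus WT_WASHOUT), 14 to 86 (APP-PS1_UA-WASHOUT minus APP-PS1_WASHOUT), 7 to 20 (APP-PS1_UA minus WT_CTR), 11555 to 13113 (APP-PS1_UA-WASHOUT minus WT_WASHOUT), 1 to 28 and 3845 to 5983 (stage differences of urolithin A and the transgenes). The correlations ran from -0.034 to 0.075 (transgene) and -0.135 to 0.025 (urolithin A), and the score differences from -0.04 to 0.20 and -0.06 to -0.03. Of 1655 named-gene results tested this way 1472 stayed on their side of the threshold, 175 missed it, 8 newly passed and 0 reversed. They include genes that were not called, such as Apoe at the end of treatment, for which staying uncalled counted as kept. A reversal was counted only where a call was made.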

Other observations

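The tests in this part were chosen only after the values were seen, apart from the named genes and list members, which followed the rule. The blood cell list did not pass in APP-PS1_WASHOUT minus WT_WASHOUT (4 of 12 higher, 7 above 0, median 0.68, mean 0.09, adjusted p = 0.643 by camera). Of its members Cd3e, a chain of the T cell receptor complex, rose by 1.24 (adjusted p = 8.44e-05 by limma), from -1.92 ± 0.20 (n = 5) to -0.68 ± 0.27 (n = 3), and Nkg7, a granule protein of cytotoxic cells, by 1.83 (adjusted p = 0.00146). The glutamatergic synapse list (median 0.06, adjusted p = 0.96 by camera) and the interneuron list (-0.10, 0.212) did not pass. Of the synapse list the vesicle fusion gene Snap25 was 0.75 (its other probe -0.26). Of the interneuron list the neuropeptide Sst was 0.58, against the falls of Lhx6 and Gad1 given above. The cortical and interneuron membrane protein gene Lamp5, on neither list, was -0.63. Tiparp, a target of the aryl hydrocarbon receptor, fell by 0.68, and the amino acid response gene Asns rose by 0.47. All these compare slide 3 with slide 2.

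The choroid plexus list moved as a unit. Its 14 genes correlated within groups with a median of 0.978, and transthyretin (Ttr) ranged from 0.78 to 7.80 between arrays, and its score ran higher or lower from sample to sample within each group.

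Liver transcripts stood out in WT_WASHOUT 2 and 3. A list of 20 liver genes was written after Alb, Mup1, Mup3 and Fgg, which are on it, and these arrays had been noticed, so its values are no test. Of 18 measured members 14 were highest in these arrays. Alb was 1.09 and 0.52 there and at most -4.65 elsewhere, and Mup1 was 1.93 and 1.10 and at most -3.52 elsewhere. Without both arrays Alb in APP-PS1_WASHOUT minus WT_WASHOUT was -1.02 (adjusted p = 0.353) and Mup1 -1.57 (0.167).

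The changes in APP-PS1_UA minus APP-PS1_CTR ran opposite to those in APP-PS1_CTR minus WT_CTR across genes, with r = -0.682. Both contrasts use the APP-PS1_CTR arrays, and 200 simulations with no effect in either gave r = -0.572 on average. The covariance was -0.0869 in the data and -0.0618 in the simulations. The 3 arrays of APP-PS1_CTR are too few to give each contrast its own controls, and the slides differ between the groups, so a reversal by urolithin A was not tested by this.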
